A study of Rattus norvegicus with 6 samples.

How the data were processed

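Total RNA (2 µg) of the substantia nigra pars compacta, taken by laser capture from each of 6 rats, was amplified by in vitro transcription, labelled with biotin and hybridised to CodeLink one-colour arrays, per the labels' protocols. Spikes of synthetic mRNA were added to every tube before amplification. Each rat gave 1 array, so the replicate is the animal, and the groups, 3 solvent and 3 rotenone rats, were taken from the labels. How many captured sections went into a sample is not given in the sources used here.

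For each spot the deposited scanner files give, as a linear intensity, the mean of the spot, the median of its local background, their difference, and that difference after scaling by the authors' software to about the median of the array. The scanner software and its version are not given in the sources used here. The deposited value table holds the same scaled intensity, so its scale is linear, each array is centred on a median near 1, and one-colour values have no direction. Its column medians were 0.994, 1.00 and 0.996 for solvent rats 11, 7 and 1 and 0.999, 0.998 and 0.996 for rotenone rats 16, 13 and 9. For 5 of its 6 columns 100% of the probe values equalled the scanner file within rounding. The column of solvent rat 7 did so for 0.898% of probes (r = 0.0146 across probes), while 86.6% of its rows equalled the scanner file row of the same rank, so its values stand beside the wrong probes. The table was therefore used as an alternative, both as deposited and with this column put back in probe order.

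Each array has 34345 spots: 33849 probes, 256 negative and 240 positive control spots. Probes were named by their RefSeq accession, without version, through a RefSeq gene table of the rat assembly GRCr8, used for names without coordinates. This named 4675 probes (13.8%) for 4013 genes, and the others, whose accessions that table does not hold, are unnamed here. Background was corrected with normexp (offset 50) on the spot mean and background median, control spots were left out, and log2 values were quantile-normalized between arrays. The offset pulls differences towards 0: in the simulation below, 2-fold and 4-fold changes had median fitted log2 values of 0.66 and 1.52.

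Rotenone was compared with solvent by limma's moderated test (limma 3.58.1, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over the probes tested. Probes were tested if above background, meaning not marked by the scanner as near background or masked, on at least 3 of the 6 arrays, with at least 2 values per group. A group below background on each of its arrays has a bound, given as at least a fold. It compares the other group's mean with a floored mean of this group. For the floored mean, each array takes the lowest value of a probe above background, or the probe's own value if higher. The bound concerns the means and leaves out the spread among rats. The p values are limma's; with 3 rats against 3 an exact permutation test cannot go below 0.1. A simulation with 100 probes changed 2-fold and 100 changed 4-fold among the 16708 tested recovered 18% and 76% (32.6% and 96.1% of the bright ones), with 8 false calls. Its noise was independent between probes, and no simulated array stood apart from the others. The number of arrays limits the precision.

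The tests, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The design as written leaves out spots that the scanner marked as contaminated, irregular or masked. The irregular mark turned out to cover 29.4% to 36.3% of probes per array, and 97.9% to 99.0% of probes with a net signal over 100, so that this design loses nearly all well-measured genes: 4283 probes and 588 named genes stayed, against 16708 and 2263 with every spot kept. After these frequencies were seen, and before any comparison of the groups, the setting that keeps every spot, listed beforehand as another processing, was chosen to lead the text. The values of the design as written are given beside it.

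Of 28 gene lists with 784 genes, 428 genes were on the array by name. Lists were tested with camera on 1 probe per gene, that with the highest mean, with a preset correlation between genes of 0.01, over lists with 5 or more measured genes. The named genes are, first, up to 12 per direction with an adjusted p below 0.05 and no overlap between groups. Places left were filled from genes at an unadjusted p below 0.01, without overlap and above background on the 3 arrays of the higher group. Then follow the 2 genes with the lowest p of each list, of which those above an unadjusted p of 0.05 may be left out, and fixed genes that include Th, Slc6a3, Slc18a2, Ddc, Aldh1a1, Nr4a2, Nqo1, Hmox1, Gfap, Aif1, Mbp and Gad1. Aldh1a1 had no named probe, and Hmox1 was above background on too few arrays to be tested. Of the genes taken by this rule, 2 are not reported here.

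Alternatives were median scaling, cyclic loess, subtraction with a floor of 1, a pseudocount of 16, no filter on dim probes, a filter on all 6 arrays, the deposited table, variance models with a trend or array weights, an unmoderated test, a threshold of 0.10, lists with estimated correlation or averaged probes, and leaving out each rat. The file header gives a day: solvent rat 7 alone differs from the other 5 arrays, so the day cannot be told from this rat.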

Results

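Gene expression was measured in the substantia nigra pars compacta of 6 male Sprague Dawley rats, 5 months old. This midbrain region holds the dopamine neurons that project to the striatum and that are lost in Parkinson disease. Minipumps placed under the skin delivered rotenone, a plant-derived inhibitor of respiratory complex I, at 0.5 mg/kg per day to 3 rats for 28 days. The other 3 rats received the solvent (dimethylsulfoxide and polyethylene glycol) in the same way. The region was isolated by laser capture, and the RNA of each rat was hybridised to 1 one-colour array. The question was whether a lasting low dose of this pesticide changes gene expression in the region. Each array carried 33849 probes, of which 4675 could be given a gene symbol, for 4013 genes. Between 44.2% and 51.5% of probes were above background on an array, and 16708 probes, covering 2263 named genes, were so on at least 3 of the 6 arrays.

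No named gene passed the test between rotenone and solvent, and Th, Slc6a3 and Ddc, the brightest markers of dopamine neurons, differed by 0.12, -0.20 and 0.07 on the log2 scale. Ribosomal protein genes and general neuron markers were lower with rotenone as lists, by medians of -0.42 and -0.20, in a test that takes the genes as nearly independent. With the correlation between genes estimated from the data, the adjusted p was 0.729 for both. Without rotenone rat 16 neither passed, at medians of -0.17 for the ribosomal and -0.185 for the neuron list. With every spot kept, 0 of 16708 probes passed an adjusted p of 0.05 in limma's moderated test (Benjamini-Hochberg), and the smallest adjusted p was 0.895. At an unadjusted p below 0.05 there were 825 probes, where chance gives 835, and at p below 0.01 there were 114, where chance gives 167. Of these 114, 53 were higher and 61 lower with rotenone, and with medians of the arrays equalised instead, 26 were higher and 122 lower. The ordinary test without moderation also called 0 probes. Of all probes, 95.6% differed by less than 0.5 on the log2 scale, 20 differed by more than 2-fold, and the 3 rotenone values did not overlap the 3 solvent values at 9.97%, where chance gives 10%. In the design fixed beforehand, which left out spots marked by the scanner, 4283 probes could be tested, and 2 of them, neither with a gene name, were called higher with rotenone. That design gave 52 probes at an unadjusted p below 0.01 (chance 42.8; 18 higher and 34 lower, but 30 higher and 22 lower with cyclic loess) and 260 below 0.05 (chance 214). In a simulation on the 16708 probes, the same test found 76% of 4-fold changes and 18% of 2-fold changes. Most 2-fold changes were thus not detectable there, with 3 rats per group and an offset that drew them to a median fitted log2 of 0.66. The simulated probes had independent noise and no array stood apart, so recovery in the real data may differ.

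Of the markers of dopamine neurons, Th, Slc6a3, Ddc and Cck were bright in both groups, while others such as Pitx3 (6.14 with solvent, 5.97 with rotenone) and Foxa2 lay near background. None of the 15 measured passed the test, over all probes or adjusted over the list alone (smallest adjusted p 0.253). Tyrosine hydroxylase (Th, probe GE1254069), the rate-limiting enzyme of dopamine synthesis, had a normalized log2 intensity of 12.74 ± 0.22 (SD, n = 3) with solvent and 12.85 ± 0.27 (n = 3) with rotenone. Its difference was 0.12, with a 95% interval from -0.32 to 0.55. The dopamine transporter Slc6a3 differed by -0.20 (interval -0.54 to 0.15), and Ddc, which makes dopamine from its precursor, by 0.07 (interval -0.50 to 0.64). With a rat left out, the difference of Th lay between -0.01 and 0.27 and that of Ddc between -0.10 and 0.31. The vesicular monoamine transporter Slc18a2 was at 9.63 ± 0.22 with solvent and 9.08 ± 0.56 with rotenone, a difference of -0.54 with an interval from -1.13 to 0.05, and -0.26 without rotenone rat 13 and -0.82 without rotenone rat 9. The transcription factor Nr4a2, needed for the dopamine phenotype, differed by -0.79 ± 0.32 (SE), and gamma-synuclein (Sncg) by -0.67 ± 0.23. Their unadjusted p values in limma were 0.0343 and 0.0169 and the adjusted p was 0.895 for both. Nr4a2 was above background on 3 solvent and 2 rotenone arrays, and lay at 5.94 in rotenone rat 16. Without rotenone rat 16, whose array stood apart from the others, the difference of Sncg was -0.37 and that of Nr4a2 was -0.47, and without rotenone rat 9 that of Nr4a2 was -1.22.

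As a list, the dopaminergic markers had a median log2 change of -0.00064 and a mean of -0.13, with 7 genes higher and 8 lower. Camera, a test of a list against the other genes, gave an adjusted p of 0.477. The median deviation of the list from the solvent mean was -0.13, -0.17 and -0.06 in the 3 rotenone rats and between -0.00491 and 0.02 in the 3 solvent rats. Each solvent rat is part of that mean, which draws the solvent deviations towards 0. The narrow solvent range is therefore no measure of the spread among rats. Without rotenone rat 16 the median change was -0.16 (adjusted p 0.133). For Gfra1, a receptor of the glial cell line-derived factor GDNF, singled out after its values were seen, 2 probes disagreed. The brighter one, GE1306066, differed by 0.00405, and GE22011 differed by -0.86 (unadjusted p 0.00709 in limma). In the design fixed beforehand, 4 genes of the list were measured, with a median change of -0.07, and Ddc differed by 0.32 ± 0.18 (SE).

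**Figure D1:**
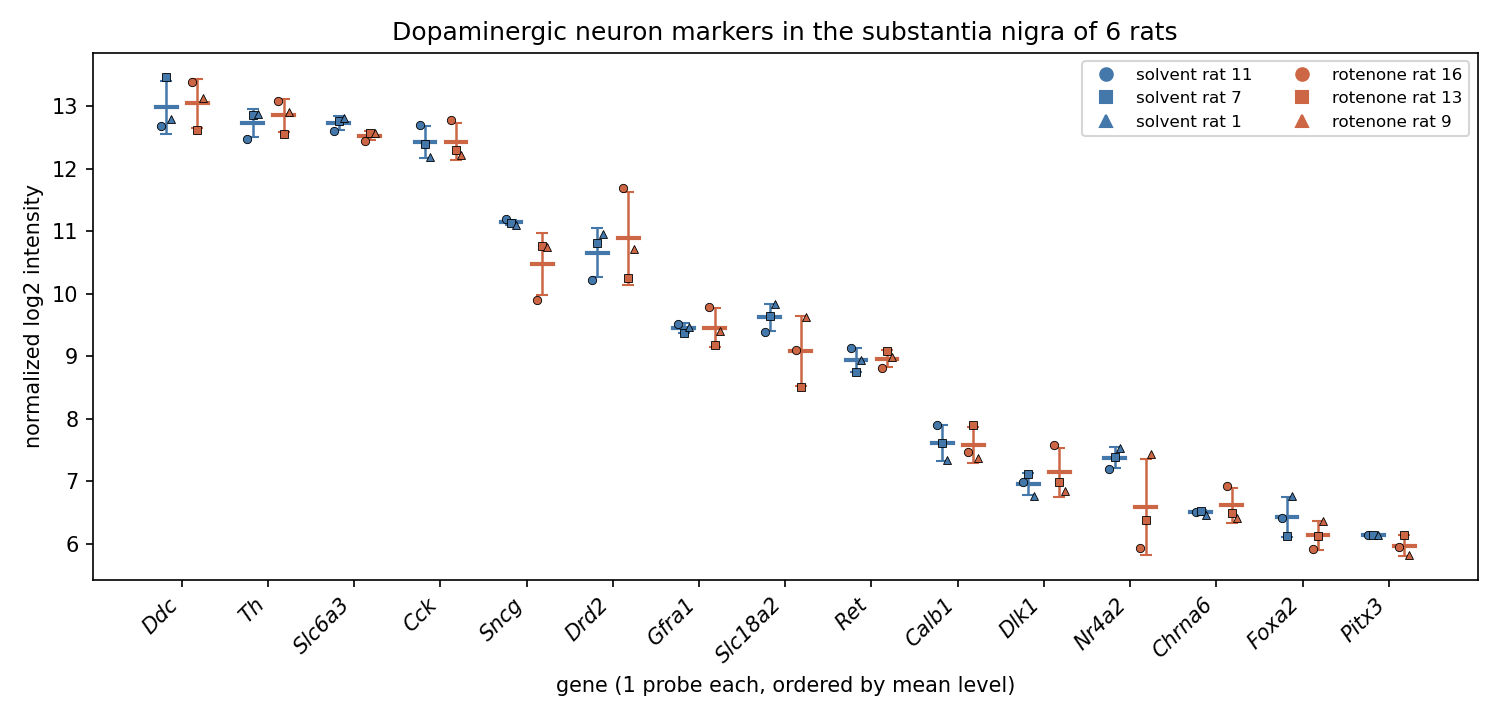
Normalized log2 intensity (vertical axis) of the 15 dopaminergic markers measured (horizontal axis), with a point per rat, and the mean and SD of the 3 solvent rats (blue) and 3 rotenone rats (orange). Th had means of 12.74 and 12.85, and the largest differences in means were those of Nr4a2, at -0.79, and Sncg, at -0.67.

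Respiratory complex I is the target of rotenone, and 2 genes of its subunits could be named and measured, too few for a list test. Ndufa5 differed by 0.19 (95% interval -0.17 to 0.55) and Ndufv3 by 0.11 (interval -0.36 to 0.58), and their median was 0.15. Ndufv3 lay near background (6.23 with solvent, 6.34 with rotenone), above it on 2 arrays of each group. The 19 measured genes of respiratory complexes II to V had a median change of -0.20, with 14 lower and 5 higher and an adjusted p of 0.243 for the list. Their median without rotenone rat 16 was -0.03. None of the genes in either list passed the test. In the design fixed beforehand 1 complex I gene was measured, Ndufv3, at 0.07.

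Ribosomal protein genes were lower as a list in the rotenone group. Of 25 measured, 21 were lower and 4 higher, the median log2 change was -0.42, and camera gave an adjusted p of 0.00386 with a preset correlation between genes of 0.01. With the correlation estimated from the data, at 0.440, the adjusted p was 0.729. None of the 25 genes passed the test alone, and Rpl10a had the smallest unadjusted p in limma (0.0277; 7.74 ± 0.05 against 6.94 ± 0.75, SD, n = 3 each), followed by Rpl3 with a difference of -0.43 ± 0.19 (SE). Without rotenone rat 16 the differences of Rpl10a and Rpl3 were -0.37 and -0.25. The difference lay mostly in 1 animal: the median deviation from the solvent mean was -0.84 in rotenone rat 16, -0.07 in rat 13 and -0.14 in rat 9. Without rat 16 the median change was -0.17 with an adjusted p of 0.208, and without solvent rat 11 it was -0.36 with an adjusted p of 0.0776. With medians of the arrays equalised instead of quantile normalization, the median change was -0.42 and the adjusted p 0.0649.

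The general neuron markers were also lower as a list. All 10 measured genes had lower means with rotenone, with a median change of -0.20 and an adjusted p of 0.0263, and an adjusted p of 0.729 with an estimated correlation. The neurofilament-family gene Ina (alpha-internexin) differed by -0.78 ± 0.29 (SE), the growth cone protein gene Gap43 by -0.50 ± 0.19 and the synaptic vesicle gene Syn2 by -0.40 ± 0.17. The second probe of Gap43 differed by -0.97. Their adjusted p was 0.895. The median deviation was -0.66 in rotenone rat 16, -0.07 in rat 13 and -0.19 in rat 9, and -0.20 in solvent rat 1. Without rat 16 the median change was -0.185 with an adjusted p of 0.179, and the difference of Ina was -0.48. The median was -0.39 without rotenone rat 13 (adjusted p 0.0489) and -0.34 without solvent rat 1 (adjusted p 0.00753). Leaving out solvent rat 11 or solvent rat 7 also ended the call, at medians of -0.21 and -0.18 and adjusted p values of 0.123 and 0.0951. So did equalising the medians of the arrays, at a median change of -0.31 and an adjusted p of 0.0649 in camera. Proteasome subunit genes had a median of -0.29, 18 of 22 lower, with an adjusted p of 0.0535, and -0.07 without rat 16.

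**Figure D2:**
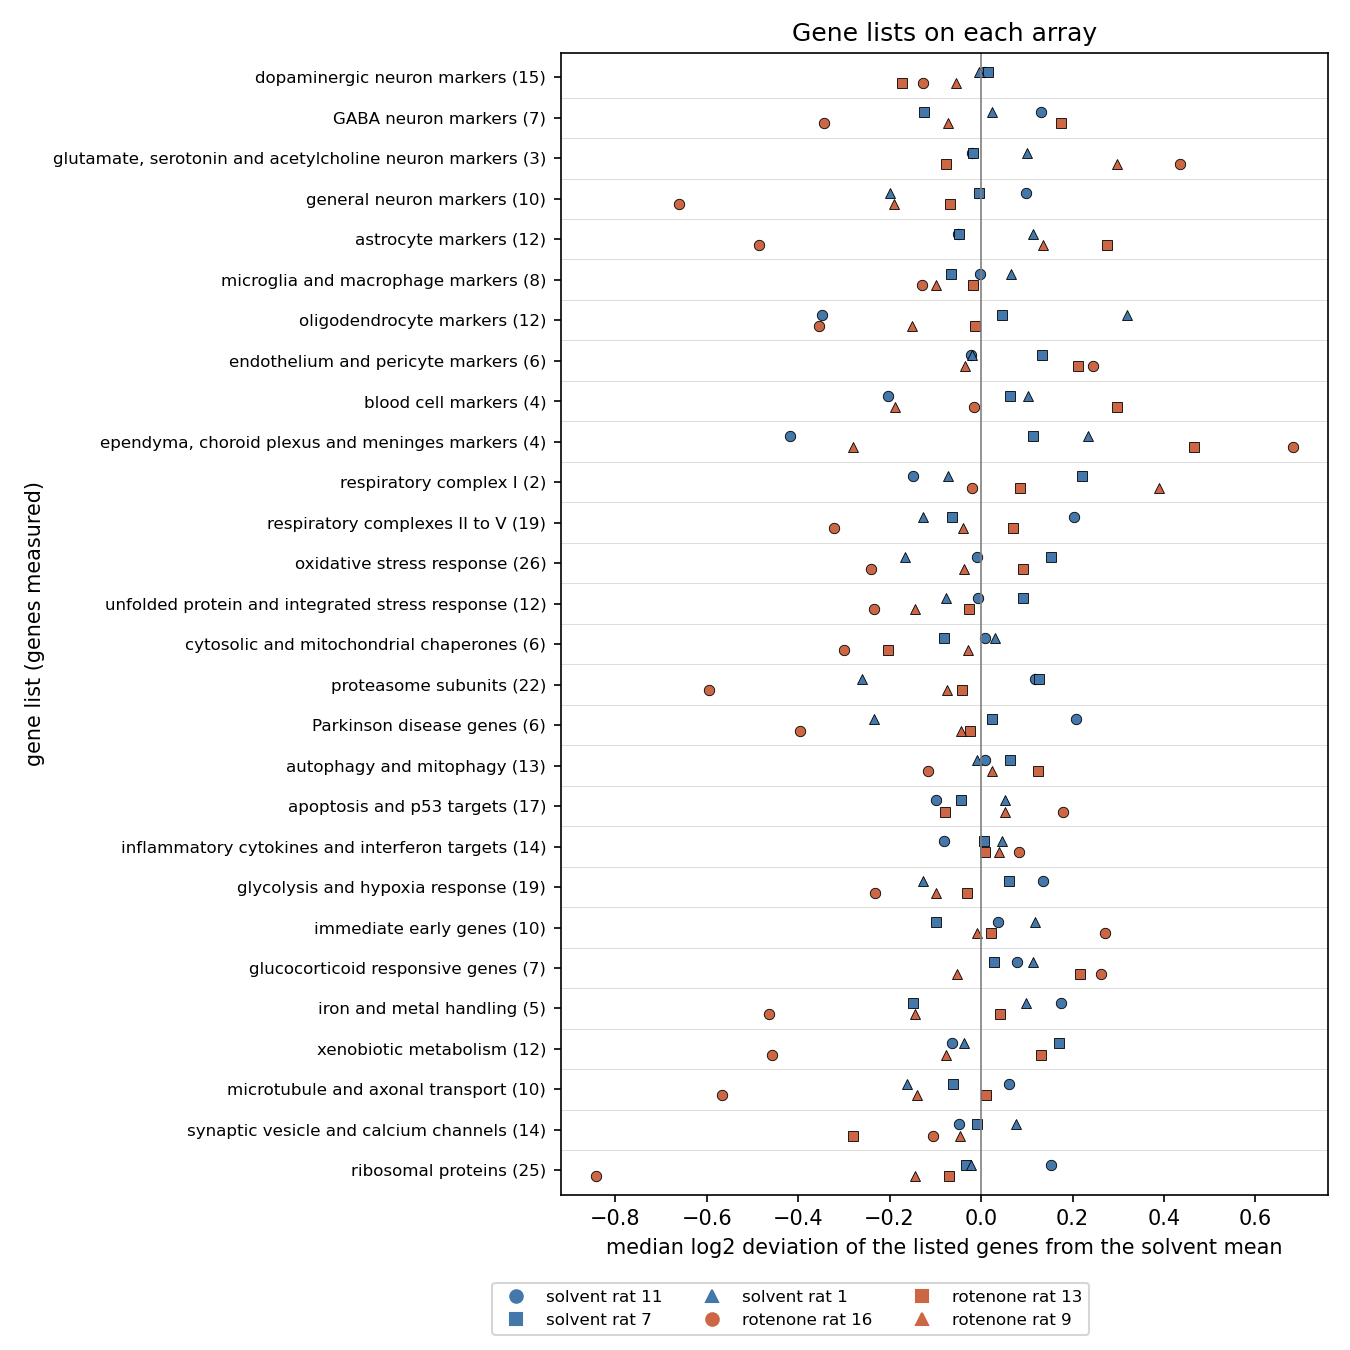
Median log2 deviation of the genes of each list from the mean of the solvent rats (horizontal axis), for 28 lists (vertical axis, with the number of genes measured) and 6 rats (points). Rotenone rat 16 lay at -0.84 for the ribosomal proteins, -0.66 for the general neuron markers and -0.59 for the proteasome subunits, apart from the other 5 rats.

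None of the other lists passed the test. The glia markers gave a median of -0.07 for 12 astrocyte genes (adjusted p 0.477; 6 higher, 6 lower), -0.04 for 8 microglia and macrophage genes (adjusted p 0.999) and -0.13 for 12 oligodendrocyte genes (adjusted p 0.477). Gfap, the astrocyte filament gene, differed by -0.15 (95% interval -0.85 to 0.55), the microglial gene Aif1 by -0.06 (interval -0.40 to 0.27), and the myelin gene Mbp by -0.38 (interval -0.94 to 0.18). With a rat left out, the difference of Gfap lay between -0.48 (without rotenone rat 13) and 0.16 (without rotenone rat 16), and that of Mbp between -0.68 (without solvent rat 11) and -0.21 (without solvent rat 1). Mal, another myelin gene, differed by -0.66 ± 0.27 (SE), and by -0.34 without rotenone rat 16. The astrocyte list moved with the array of rotenone rat 16, which lay at -0.49, against 0.28 in rat 13 and 0.14 in rat 9, and its median change without this rat was 0.20 with an adjusted p of 0.0731. GABA neuron markers had a median of -0.03 (n = 7, adjusted p 0.824). Gad1, which makes the transmitter GABA, differed by -0.03 (interval -0.38 to 0.33) and Gad2 by -0.41 ± 0.17. Gad2 lay near background, above it on 2 solvent arrays and 1 rotenone array. Markers of endothelium and pericytes had a median of 0.16 (6 genes, adjusted p 0.305). Markers of blood cells (median -0.10, 4 genes), of ependyma, choroid plexus and meninges (0.24, 4 genes) and of glutamate, serotonin and acetylcholine neurons (0.36, 3 genes) were too few for the test.

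The stress lists were mixed. Of 26 oxidative stress genes, 9 were higher and 17 lower (median -0.04, adjusted p 0.999). Txnrd1, which keeps thioredoxin reduced, differed by 0.56 ± 0.19 (SE) and the secreted superoxide dismutase Sod3 by 0.66 ± 0.24. Nqo1, a target of the factor NRF2, differed by -0.09 (95% interval -0.49 to 0.31). It lay near background (6.20 with solvent, 6.11 with rotenone), above it on 2 solvent arrays and 1 rotenone array. Among iron and metal genes the ferritin heavy chain Fth1 differed by -0.83 ± 0.27 and the metallothionein Mt3 by -0.70 ± 0.30, with an adjusted p of 0.0572 for the list alone as the smallest value, and the rat 16 array lay at -0.46 for this list of 5 genes. The endoplasmic reticulum gene Pdia3 (-0.64 ± 0.26), the small heat shock gene Cryab (-0.62 ± 0.26), the mitochondrial aldehyde dehydrogenase Aldh2 (-0.77 ± 0.27) and the tubulin Tuba1a (-0.74 ± 0.33) were lower in mean. The autophagosome gene Map1lc3b (0.39 ± 0.17) and the phosphatase gene Dusp1 (0.41 ± 0.16), which responds early to glucocorticoids and other stimuli, were higher in mean. Each of these had an unadjusted p below 0.05 in limma and an adjusted p of 0.895. Without rotenone rat 16 the differences of Mt3, Pdia3, Cryab and Aldh2 were -0.34, -0.35, -0.32 and -0.49, and without solvent rat 7 that of Tuba1a was -0.37. The lists of the unfolded protein response (median -0.13, 12 genes), chaperones (-0.16, 6 genes) and inflammatory cytokines and interferon targets (0.10, 14 genes) each had an adjusted p of 0.291, as had the synaptic vesicle and calcium channel genes (-0.16, 14 genes). Genes of autophagy and mitophagy (0.03, 13 genes), apoptosis (0.03, 17 genes), glycolysis and hypoxia (-0.11, 19 genes), iron and metal handling (-0.02) and xenobiotic metabolism (-0.08, 12 genes) each had an adjusted p of 0.477. The adjusted p was 0.244 for immediate early genes (0.12, 10 genes), 0.205 for glucocorticoid responsive genes (0.09, 7 genes) and for microtubule and axonal transport genes (-0.25, 10 genes), and 0.395 for Parkinson disease genes (-0.16, 6 genes). For the astrocyte and oxidative stress lists camera's direction was up although the median was below 0, and for autophagy the mean was -0.03 although the median was above 0.

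The rule fixed beforehand, which takes genes with non-overlapping groups at an unadjusted p below 0.01, gave 3 genes with higher and 9 with lower values, and none of them passed the adjusted test. Some genes outside it, such as Fth1 and Nr4a2, had larger differences than most of these. Cdon, a cell surface co-receptor of hedgehog signalling, differed by 2.06 ± 0.54 (SE). It was at 5.95 and 5.92 in solvent rats 11 and 7, below background, at 8.42 in solvent rat 1 and between 8.79 and 8.90 in the rotenone rats. The cadherin gene Cdh23 differed by 0.66 ± 0.20 and Icam1, an adhesion molecule for leukocytes, by 0.53 ± 0.16. Icam1 lay near background (6.20 with solvent, 6.74 with rotenone), above it on 2 solvent and 3 rotenone arrays. Among the lower genes were Yif1b, of transport between the endoplasmic reticulum and the Golgi (-0.89 ± 0.19), the splicing factor gene Bud31 (-0.80 ± 0.24; -0.56 at its second probe, and -0.53 at the first without rotenone rat 16), the syntaxin Stx4 (-0.68 ± 0.21) and Bckdk, a kinase of branched-chain amino acid breakdown (-0.67 ± 0.17). Dnm2 (-0.58), Scamp4 (-0.57), both of membrane traffic, and Insig2 (-0.54), a regulator of sterol synthesis, followed. Coagulation factor F10 and Mal2 were not well above background in any rotenone rat, and were at least 1.69-fold and 1.43-fold higher with solvent.

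In the design fixed beforehand the genes named by the same rule included Acsl4 (2.53 ± 0.55, SE) and Ywhag (1.16 ± 0.30) as higher and Rps6kb1 (-0.52 ± 0.15), Pdgfrb (-0.47 ± 0.13), Cap1 and Nat1 as lower, again with none past the adjusted test (adjusted p from 0.641 to 0.775 in limma). Cap1 and Nat1 were not well above background in any rotenone rat and were at least 1.19-fold and 1.30-fold higher with solvent. There, Ywhag and Rps6kb1 rested on 2 values per group, and Acsl4 and Pdgfrb on 3 solvent and 2 rotenone values. With every spot kept, the differences of Acsl4, Ywhag, Rps6kb1 and Pdgfrb were 0.14, 0.36, -0.24 and -0.20. The 3 lists that had 5 genes or more in the design fixed beforehand, on apoptosis, inflammation and immediate early genes, each had an adjusted p of 0.593.

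The array of rotenone rat 16 differed from the other 5 more than they did among themselves. Its mean correlation with the other arrays, across probes, was 0.931, against 0.956 to 0.964 for the others. It had a score of 46.8 on the first principal component, which held 42.7% of the variance, where the others lay between -18.6 and -0.48. Its median net signal was the lowest, at 11.7, against 13.9 to 16.6. The synthetic spike RNA added before amplification gave a median net signal of 216 on this array and of 890 to 2050 on the others. Without this rat, 98 probes of the fit with every spot kept had an unadjusted p below 0.01 and 0 passed the adjusted test.

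**Figure D3:**
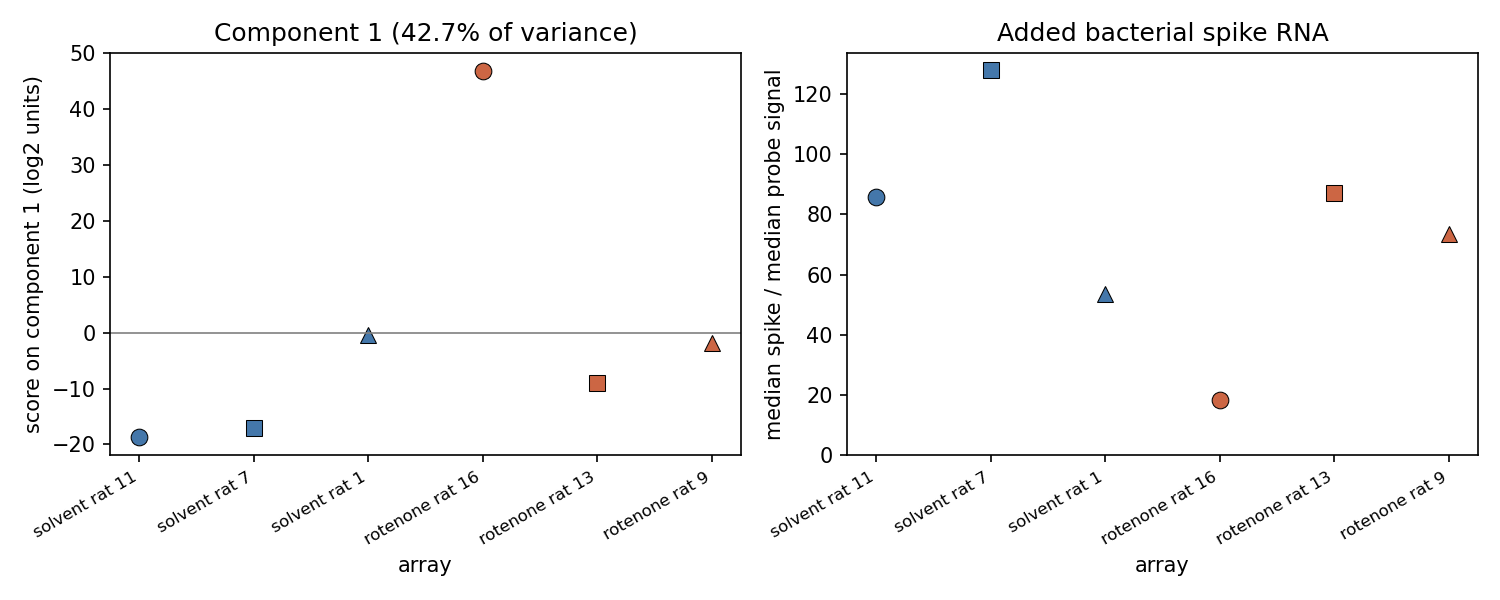
Score on the first principal component (left panel) and ratio of the median spike signal to the median probe signal (right panel, no unit) for each of the 6 arrays (horizontal axis). Rotenone rat 16 had a score of 46.8 and a ratio of 18.4, where the other arrays lay at -0.48 or below and at 53.5 or above.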

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

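The alternatives computed with every spot kept, beyond that setting itself, and the realigned table were chosen after seeing the data. With every spot kept, 0 probes passed, as under each alternative except without solvent rat 1 (3 probes, all higher; 0 to 3 with a rat left out) and in the design as written (2 probes). The probes at an unadjusted p below 0.01 numbered 114, and 284 without a filter on dim probes, 67 with all 6 arrays above background, 8 in the deposited table and 69 (without solvent rat 11) to 218 (without rotenone rat 13) when a rat was left out. The filters changed the number of probes tested, to 33849 and 12468. The realigned table gave 124, so the misplaced column of solvent rat 7 lowered the count of the deposited table. The number of lists called was 2, and 0 with median scaling, with an estimated correlation, in the deposited table and in the realigned table, 1 with the day as a block, and 0 (without solvent rat 11 or rotenone rat 16) to 3 with a rat left out. Where 3 lists were called, as with loess or no filter on dim probes, the third was the proteasome list. In the deposited table as it stands the ribosomal list turned to 1.74 and the general neuron list to 0.74, where the median of all genes moved to 0.75 by the misplaced column, and after realignment they were -0.26 and -0.34.

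The median of the dopaminergic list, -0.00064 with every spot kept, was -0.078 with median scaling, 1.40 in the deposited table, 0.10 in the realigned table, -0.039 with the day as a block, -0.037 with averaged probes and -0.16 to 0.027 with a rat left out; none of these passed the test. Complex I, at 0.15 for 2 genes, was -0.12 in the deposited table, 0.47 in the realigned one, 0.34 with subtraction, 0.26 with the day as a block and 0.032 (without rotenone rat 9) to 0.26 (without solvent rat 7) with a rat left out.

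In the design as written, 2 probes passed, and 0 with median scaling, cyclic loess, subtraction, a trend in the variance, the unmoderated test or either table, 1 with the pseudocount or with all 6 arrays above background, 7 with the day as a block (3 higher, 4 lower), and 0 to 7 with a rat left out (7 without solvent rat 11). With every spot kept this became 0. The day block holds solvent rat 7 alone, so that fit sets the rotenone rats against solvent rats 11 and 1. For some probes, such as that of Ddc, only 1 of these had a value. Leaving solvent rat 7 out instead gave 0 of 2623 probes. The probes at p below 0.01, 52 of 4283 tested, became 235 of 21272 without the filter on dim probes. They became 8 of 993 with all 6 arrays above background. There were 8 in the deposited table, 124 in the realigned one and 114 with every spot kept, each of 16708. With a rat left out there were 20 to 54, of 2623 to 3149 tested. Chance gives a share of 0.01 of the probes tested. No list was called, against 2 with every spot kept. The dopaminergic median, -0.070 over 4 genes, was -0.029 with loess, -0.42 with subtraction, -0.17 with the pseudocount, 0.0098 without the filter, 0.16 with all 6 arrays above background, 1.40 and 0.10 in the deposited and realigned tables, -0.00064 with every spot kept and -0.11 to 0.083 with a rat left out. Complex I, 0.07 for 1 gene, was 0.42 with subtraction, and -0.12 and 0.47 in the 2 tables. The tables drop no marked spots and have neither the offset nor quantile normalization. Their values here therefore repeat those given for every spot kept, over 16708 probes, 15 dopaminergic genes and 2 complex I genes. In the design as written, subtraction and the pseudocount moved the median of all genes to -0.22 and -0.11. The cause of the other shifts was not tested.

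Of 1475 recomputed differences of named genes with every spot kept, 1331 moved by less than 1 SD of replicates, 143 by more, and 1 passed the threshold (Cdon without solvent rat 1, where both solvent values left were below background). In the design as written Acsl4 passed without solvent rat 11, the solvent rat with its highest value (log2 change 2.91, adjusted p 3.51e-05). Its difference over all rats was 2.53 in that design, on 3 solvent and 2 rotenone values. With every spot kept it was far smaller, as given in the Results, and under the bound of 0.5 set for the 2 unnamed probes. That fall goes with quantile normalization over arrays with most bright spots missing as the source of this call. No bound was set for Acsl4 and the explanation was not tested for it, so it stays open. With a rat left out, the design as written still tested 1 to 3 lists, and with all 6 arrays above background it tested 0. The medians of the dopaminergic and complex I lists had no value there without some rats. Signal over background limits both: between 48.1% and 55.2% of probes were near background on an array.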

Other observations

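In the tests of this part, those on the 2 unnamed probes one by one were chosen after their values were seen, as was the choice of the patterns. Over the 6 rats, whatever their group, the named gene with the largest spread was Cdon (SD 1.45), followed by Acads, a mitochondrial enzyme of short-chain fatty acid breakdown. Acads was at 9.78 in rotenone rat 16 and between 6.42 and 6.69 in the other 5 rats. Ptgds, an enzyme abundant in meninges and choroid plexus, ranged from 9.04 in rotenone rat 16 to 11.94 in rotenone rat 13, and solvent rats 7 and 1 lay at 11.63 and 11.42. Igf2, also made by the meninges and choroid plexus, was lowest in solvent rat 11 (8.67) and highest in rotenone rat 13 (10.83). In rotenone rat 16, the lowest for Ptgds, Igf2 was at 10.46, so these 2 genes did not vary together. Cd74, of antigen-presenting cells, ranged from 6.53 in solvent rat 11 to 8.38 in rotenone rat 13. Several other genes of large spread were lowest in rotenone rat 16. Rpsa was at 7.06 there and between 8.66 and 9.88 in the other rats, and Gabarap at 7.70 and between 9.34 and 9.93. Hap1, like Acads, was highest in rat 16 (10.275). These are single rats, not groups.

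Rotenone rat 16 stood apart from the other 5 arrays, and a technical reason was weighed against a stronger response to rotenone. A local defect is argued against by the rows of the array: the median deviation over 8 bands of rows had a range of 0.0565, within the 0.0301 to 0.0775 of the other arrays. A weaker signal acting on dim probes is argued against by the brightest 25% of probes, where the spread of this array's deviation from the rest was 1.84 times the median of the same spread on the other arrays. Low sample signal in general stays open, since the spikes meant to gauge it were themselves lowest here (0.144 of the highest ratio to probes), and so does another cell mix in the captured tissue, where the general neuron markers lay at percentile 0.57 of random lists matched on intensity, short of the 0.5 set for a clear case. A stronger response to rotenone may also play a part: differences that share no array correlated at 0.0855 across probes on average (-0.0929 to 0.215 by pair), between the bounds set for and against it, so these explanations cannot be told apart.

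The lower ribosomal protein and neuron genes in the rotenone group were weighed in the same way. For the ribosomal list a shift of bright probes is argued against. Its median lay below those of 10000 random gene lists matched on intensity (percentile 0, central range -0.17 to 0.10). Random lists lack the correlation between ribosomal genes, estimated at 0.44. The percentile therefore sets the list against genes of like intensity and is not a p value. The general neuron median, -0.20, lay at percentile 2.9 of its random lists, inside their central range of -0.21 to 0.12. For the neuron list a shift of bright probes therefore stays open. Whether rat 16 alone carried the ribosomal part cannot be told, with a median of -0.17 without it, between the bounds of -0.1 and -0.2 set in advance, while the general neuron median was -0.185 without it and lost its call, and ranged from -0.39 (without rotenone rat 13) to -0.18 (without solvent rat 7) with a rat left out. An effect of rotenone therefore stays open, as does a difference of this one sample, for both lists. For the neuron list no bound was set, and its median deviation was -0.66 in rat 16. It was -0.07 in rat 13 and -0.19 in rat 9, within the solvent range of -0.20 to 0.10. That range is drawn towards 0, since the solvent rats make up the mean. With 10 splits of the 6 arrays into 3 and 3 a share under 0.05 cannot be reached: the real split called 2 lists, 6 of the 10 splits called as many or more, and the highest other called 5.

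Of the 2 unnamed probes called in the design as written, GE1275290, with a log2 change of 3.21 there, was at -0.46 with every spot kept. Its net signals were 3166 and 4083 in the 2 solvent rats used and 3894 and 2897 in the 2 rotenone rats, so its call is likely a product of quantile normalization over arrays with most bright spots missing. Probe GE1154059 was at 2.40 and then at 0.92 (unadjusted p 0.0461 in limma), between the bounds of 0.5 and 1 set for and against this explanation, which stays open for it. Its net signal was highest in solvent rat 1 (200, against 107, 135 and 148 in rotenone rats 16, 13 and 9), while its normalized value in the design as written was lower there (7.15, against 8.80 to 9.26), and solvent rats 11 and 7 had net signals of 15.5 and 9.6. Of the 10 splits, 3 gave 2 or more called probes, and the highest other gave 3.

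For the other counts the 10 splits again cannot give a share under 0.05. In the design as written the real split had 52 probes at an unadjusted p below 0.01 and the highest other had 54, with 3 splits as high. With every spot kept the real split had 0 called probes and 114 at p below 0.01, and the highest others had 2 and 358. As many or more were found in 10 splits and in 5.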
